A study of Ovis aries with 46 samples.

How the data were processed

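RNA was extracted from abomasal lymph nodes with TRIzol and sequenced as single reads with Illumina kits, per the labels' protocols. Reads of each library from 3 flow cells were combined before counting, per the labels, and each library carried 1 of 6 index tags. Library preparation of 2 day 7 samples failed and 2 day 21 samples were not prepared, per the labels. The deposited unit is the read count per gene, and the submitters' processing notes name Bowtie, SAMtools, HTSeq and edgeR without versions or roles. The gene IDs begin with ENSBTAG, the Ensembl prefix for cattle genes, so reads of sheep were counted on cattle genes. The genome build, the release of the annotation, and whether counting used strand are not given in the sources used here. Where genes overlap or have near-identical copies, the counts cannot say which of them the reads came from.

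Each of the 46 files holds counts of 24616 gene IDs and 5 summary lines. Of all reads in a library, 29.2% to 32.9% (mean 31.1%) were assigned to genes, 44.2% to 47.9% (mean 45.6%) were not aligned, 21.0% to 25.6% (mean 23.2%) lay outside annotated genes and at most 0.0509% were ambiguous. The summary lines for low alignment quality and for reads with more than 1 alignment were 0 in all libraries. These lines stayed out of library sizes and tests. Libraries held 9.39 to 27.1 M reads in all. The 85 pairs of libraries within groups differed by more than sampling noise (chi-square per degree of freedom from 2.85 to 20.9 over genes with at least 20 reads in the pair), so none was treated as a repeat of another. Each library is a separate animal. Replicates are named by animal number, and no number recurs in a second group.

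Groups were breed and day, 10 in all. Counts were analysed in R 4.3.3 with edgeR 4.0.16: filterByExpr kept 13199 gene IDs, and libraries were scaled by TMM (factors from 0.964 to 1.03). A quasi-likelihood model with robust dispersion was fitted to all 46 libraries with 1 mean per group and 36 residual degrees of freedom. The common dispersion was 0.0222, a biological coefficient of variation of 14.9%. Contrasts compared each infected day with day 0 over the mean of both breeds and within each breed, Texel with Suffolk over the mean of all days and at each day, and the breed by day interaction. A gene passed at a Benjamini-Hochberg adjusted p under 0.05, two-sided. Standard errors of log2 fold changes were taken from the fold change and the test statistic. CPM are counts scaled to the TMM-adjusted library size in M, given as mean ± SD over lambs, and log2 CPM used a prior count of 2.

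The rule for named genes and 41 gene lists, fixed before the data were examined, needed gene symbols. The reference table used here covers sheep genes (assembly ARS-UI_Ramb_v3.0) and matched 0 of the gene IDs, which are those of cattle genes. The files do not pair IDs with names, and no table of cattle gene names was used. The rule and the lists, with their enrichment tests, were therefore not applied. In their place, the 2 genes with the largest increase and the 2 with the largest decrease are given for each of 5 broad comparisons, among genes past the test with a mean log2 CPM of at least 1. Groups with 1 to 3 reads of a gene are compared by a ratio of reads with an exact 95% interval, which covers counting error only. The interactions at single days and the contrasts between infected days were added after the data were examined.

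Alternatives set before the data were examined were scaling by the DESeq2 size factors, DESeq2 1.42.0 in place of edgeR, no low-count filter, a fit to the compared groups only, the index tag as a factor, and each library left out in turn. Added later were the joint removal of Suffolk day 0 animals 5 and 10, and terms for lower against higher animal numbers within each day. Shares of reads were compared with exact permutation tests, or with 100000 resamples where both groups held 10 lambs (scipy 1.17.1). Up to 100 splits of the libraries, the real one included, were counted for each comparison.

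The model was tested on simulated data with 200 changed genes among 13199. The dispersion was set at 1.5 times the fitted trend, which lowers recovery. Genes were drawn independently, without outlying lambs or sets of genes that vary together, which may raise it. The rates may therefore be better or worse than in the real data. For day 7 against day 0 over both breeds it recovered 58.2% of 1.5-fold, 95.5% of 2-fold and 95.5% of 3-fold changes, with 8.29% false calls. Within Texel it recovered 35.8%, 86.6% and 92.4% at day 7, and within Suffolk 23.9%, 70.1% and 90.9%. For the interaction over all days, simulated as a change in Texel at day 7 only, it recovered 10.4%, 47.8% and 83.3%. For the interaction at day 7 it recovered 8.96%, 47.8% and 80.3% (2.99%, 26.9% and 74.2% without Suffolk day 0 animals 5 and 10). For the breeds averaged over days it recovered 88.1%, 94.0% and 100%.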

Results

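Messenger RNA was measured in the abomasal lymph node of 46 lambs. This node drains the abomasum, the glandular stomach of sheep, where the nematode Teladorsagia circumcincta develops. Lambs of the Texel and Suffolk breeds were about 20 weeks old when they were assigned at random, within breed, to a day of slaughter. The 10 lambs of day 0 stayed uninfected, and 36 lambs received a single oral dose of infective larvae and were slaughtered 3, 7, 14 or 21 days later. The Texel groups held 6, 5, 4, 5 and 4 lambs at days 0, 3, 7, 14 and 21, and the Suffolk groups 4, 5, 4, 5 and 4. Each library came from a different animal. Animal numbers ran in consecutive blocks by day (1 to 10 at day 0, 11 to 20 at day 3, 21 to 30 at day 7, 31 to 40 at day 14, 41 to 49 at day 21), so any processing in number order cannot be told apart from day. The total count assigned to genes ranged from 2.91 to 8.27 M per library, with a median of 4.06 M, and 15432 to 16816 gene IDs had at least 1 read. The files do not pair gene IDs with gene names, and no table of cattle gene names was used. Genes are therefore given by ID, and no pathway or cell type is named. The series title frames the question as how T cell responses relate to the resistance or susceptibility of sheep breeds to this parasite.

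Day of infection explained 55.7% of the variance of the first principal component, which itself held 11.6% of the variance of log2 CPM (counts scaled to library size). Breed explained 1.45% of that component and 67.3% of the fourth, which held 5.94% of the variance. The index tag of the library explained 7.26% and 2.62% of these components.

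The first question was which genes in the node differed between infected lambs and day 0, over both breeds. No uninfected lambs were taken at the later days, so infection cannot be told apart from age or time in any contrast with day 0. At day 3, 438 of 13199 genes tested differed from day 0 at an adjusted p under 0.05, 209 higher and 229 lower, and 30 of them changed by more than 2-fold. ENSBTAG00000030343 rose from 0.342 ± 0.295 CPM (SD, n = 10) to 3.12 ± 2.32 (n = 10), a log2 fold change of 3.11 ± 0.52 (SE; edgeR quasi-likelihood test, adjusted p = 0.000387). ENSBTAG00000020022 rose by 1.96 ± 0.46 on the log2 scale (adjusted p = 0.0114 in the same test), from 0.454 ± 0.365 CPM at day 0. ENSBTAG00000011976 fell from 54.6 ± 21.1 CPM to 16.5 ± 7.87, a log2 fold change of −1.62 ± 0.39 (edgeR adjusted p = 0.0150). ENSBTAG00000044427 had a log2 fold change of −1.58 ± 0.44 (edgeR adjusted p = 0.0359). Here 1 control library, Suffolk day 0 replicate 2, held 31.8 CPM, and the change was −0.39 (adjusted p = 0.611) without it, in a range of adjusted p from 0.00451 to 0.611 over the alternatives. The call was also lost with no low-count filter (edgeR adjusted p = 0.0571) and in a fit to the compared groups alone (0.178). Of 20 libraries left out in turn, 10 ended the call, replicate 2 included. The count of 438 fell to 206 without Suffolk day 0 replicate 5, 257 without Texel day 3 replicate 20, and 286 without Texel day 3 replicate 14. It was 156 without Suffolk day 0 replicates 5 and 10, where the call of ENSBTAG00000020022 was also lost (log2 fold change 1.75, adjusted p = 0.0702, the highest over its alternatives, the lowest being 0.00281).

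At day 7, 1516 genes differed from day 0, 893 higher and 623 lower, and 201 changed by more than 2-fold. The largest increases were in ENSBTAG00000012503, by 5.22 ± 0.66 on the log2 scale (edgeR adjusted p = 4.87e-07), and ENSBTAG00000047632, by 4.95 ± 0.48 (edgeR adjusted p = 4.86e-09). ENSBTAG00000047632 reached 1214 ± 831 CPM (n = 8) from 45.7 ± 49.6 at day 0 and 26.7 ± 34.9 at day 3, where its log2 fold change was −0.73 ± 0.47 (adjusted p = 0.443). It was above every control library in each of the 8 libraries of day 7, the lowest of which held 560 CPM against at most 162 CPM in the controls. ENSBTAG00000012503 had only 8 reads over the 10 control libraries and 255 over the 8 libraries of day 7. In Suffolk, with 2 reads at day 0, the ratio of day 7 to day 0 was 59.8 with a 95% counting interval of 16.2 to 498. That interval leaves out the spread between lambs, and the highest Suffolk library of day 7 held 24.1 CPM against a group median of 5.44. With single libraries left out, the log2 fold change over both breeds was lowest, at 4.71, without Suffolk day 7 replicate 28. The largest decreases, ENSBTAG00000042458 (log2 fold change −2.87 ± 0.70, adjusted p = 0.00529) and ENSBTAG00000044427 (−2.25 ± 0.51, adjusted p = 0.00269), rested on Suffolk day 0 replicate 2, with 103 and 31.8 CPM. Without that library they were −1.11 (adjusted p = 0.165, in a range of 0.000149 to 0.165 over the alternatives) and −1.06 (adjusted p = 0.0647, in a range of 7.58e-05 to 0.0677).

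At day 14, 1620 genes differed from day 0, 934 higher and 686 lower, with 177 changed by more than 2-fold. ENSBTAG00000012503 and ENSBTAG00000047632 had again the largest increases, by 5.01 ± 0.66 (edgeR adjusted p = 1.36e-06) and 4.80 ± 0.47 (adjusted p = 9.37e-09) on the log2 scale, the latter at 1085 ± 566 CPM (n = 10). ENSBTAG00000011666 fell from 5.59 ± 5.32 CPM to 0.459 ± 0.400, a log2 fold change of −3.38 ± 0.78 (edgeR adjusted p = 0.00355). ENSBTAG00000019379 fell from 3.84 ± 3.62 CPM to 0.364 ± 0.533, a log2 fold change of −3.15 ± 0.71 (edgeR adjusted p = 0.00249). The count was 1057 without Suffolk day 0 replicate 5 and 750 without Suffolk day 0 replicates 5 and 10.

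At day 21, 971 genes differed from day 0, 559 higher and 412 lower, with 107 changed by more than 2-fold. ENSBTAG00000047632 was at 904 ± 479 CPM (n = 8), a log2 fold change of 4.51 ± 0.47 (edgeR adjusted p = 2.11e-07), and ENSBTAG00000012503 at 3.15 ± 2.13 CPM, a log2 fold change of 4.00 ± 0.74 (edgeR adjusted p = 0.000738). ENSBTAG00000019813 fell from 108 ± 81.5 CPM to 19.9 ± 13.8, a log2 fold change of −2.32 ± 0.53 (edgeR adjusted p = 0.00628). ENSBTAG00000042458 had a log2 fold change of −2.80 ± 0.68 (edgeR adjusted p = 0.00954) with all libraries and −1.04 (adjusted p = 0.205, in a range of 0.000530 to 0.205 over the alternatives) without Suffolk day 0 replicate 2. The count was 642 without Suffolk day 21 replicate 45, 505 without Suffolk day 0 replicate 5, and 276 without Suffolk day 0 replicates 5 and 10.

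**Figure D1:**
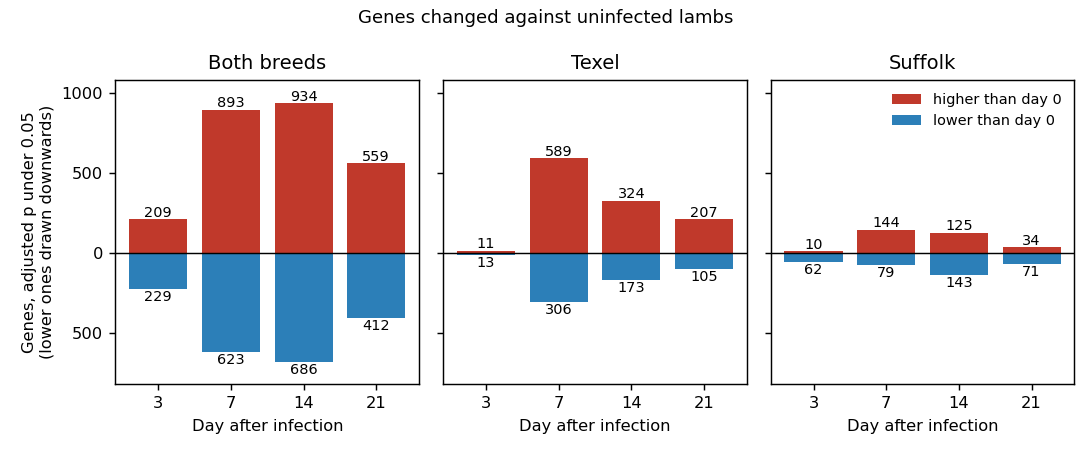
Number of genes past the test (adjusted p under 0.05, edgeR) at each day after infection against day 0, over both breeds and in each breed, with genes higher than day 0 drawn upwards and genes lower drawn downwards. Over both breeds the bars are tallest at day 7 (893 higher, 623 lower) and day 14 (934 higher, 686 lower).

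**Figure D2:**
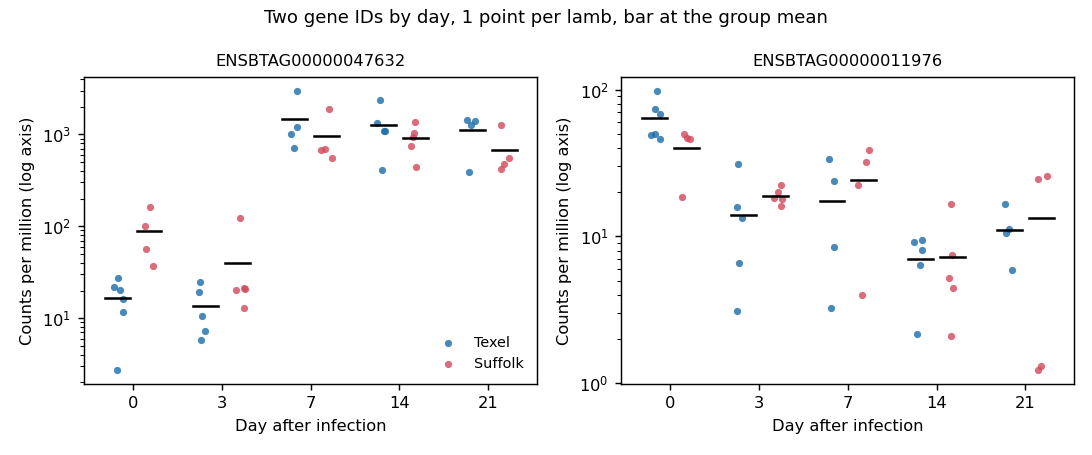
CPM of ENSBTAG00000047632 and ENSBTAG00000011976 on log axes, by day after infection and breed, with 1 point per lamb and a bar at the group mean. The first lay between 2.74 and 162 CPM in the 10 controls and between 560 and 2963 CPM in the 8 lambs of day 7, and the second between 18.5 and 97.8 CPM in the controls and between 2.11 and 16.7 CPM in the 10 lambs of day 14.

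Within the Texel breed, 24 genes differed from day 0 at day 3 (11 higher, 13 lower), 895 at day 7 (589 higher, 306 lower), 497 at day 14 (324 higher, 173 lower) and 312 at day 21 (207 higher, 105 lower). ENSBTAG00000047632 rose from 16.8 ± 8.72 CPM (n = 6) at day 0 to 1470 ± 1016 (n = 4) at day 7, a log2 fold change of 6.47 ± 0.65 (edgeR adjusted p = 4.29e-08). ENSBTAG00000011976 fell from 64.2 ± 20.0 CPM (n = 6) to 7.03 ± 2.99 (n = 5) at day 14, a log2 fold change of −3.14 ± 0.59 (edgeR adjusted p = 0.00105). ENSBTAG00000019813 fell from 129 ± 102 CPM to 9.67 ± 7.02 over the same days, a log2 fold change of −3.73 ± 0.74 (edgeR adjusted p = 0.00217). At day 3, 9 genes passed with the index tag in the model, 78 with terms for animal number, and 87 in DESeq2. At day 21, 500 passed in a fit to the compared groups alone and 203 with terms for animal number. Single libraries moved these counts by over 1.5 times: day 3 to between 7 (without Texel day 3 replicate 14) and 68 (without Texel day 3 replicate 16), and to 11 without Texel day 0 replicate 4 or 6 or Texel day 3 replicate 20, and 13 without Texel day 0 replicate 7. Day 7 fell to 465 without Texel day 7 replicate 30 and 594 without Texel day 0 replicate 8, and day 14 to 307 without Texel day 14 replicate 38. Day 21 fell to 101, 119 and 207 without Texel day 21 replicates 48, 47 and 49, and to 182 without Texel day 0 replicate 7.

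Within the Suffolk breed, 72 genes differed from day 0 at day 3 (10 higher, 62 lower), 223 at day 7 (144 higher, 79 lower), 268 at day 14 (125 higher, 143 lower) and 105 at day 21 (34 higher, 71 lower). ENSBTAG00000047632 rose from 89.0 ± 55.4 CPM (n = 4) at day 0 to 958 ± 637 (n = 4) at day 7, a log2 fold change of 3.43 ± 0.66 (edgeR adjusted p = 0.00226). ENSBTAG00000011976 fell from 40.3 ± 14.6 CPM (n = 4) to 7.18 ± 5.67 (n = 5) at day 14, a log2 fold change of −2.52 ± 0.63 (edgeR adjusted p = 0.0214). ENSBTAG00000019813 was at 76.8 ± 18.0 CPM at day 0 and 26.0 ± 23.2 at day 14, a smaller fall in the means than in Texel. The Texel controls ranged from 8.78 to 244 CPM, and the breed by day interaction at day 14 called 0 genes in edgeR. A set of 30 genes stood above the other 8 controls by more than 2-fold in both Suffolk day 0 replicates 5 and 10. To it belonged 26 of the 62 genes lower at day 3, 29 of 79 at day 7, 29 of 143 at day 14 and 26 of 71 at day 21. Without these 2 libraries the Suffolk counts were 5, 78, 24 and 13 at days 3, 7, 14 and 21, and without replicate 5 alone 0, 133, 55 and 6. In a fit to the compared groups alone they were 7, 15, 162 and 0, and with the index tag in the model 13, 133 and 4 genes passed at days 3, 7 and 21. Replicates 5 and 10 were the only day 0 libraries with their index tag, so the fit with the tag is not separate from them. DESeq2 called 113, 423 and 160 genes at days 3, 14 and 21, and with no low-count filter 39 and 63 passed at days 3 and 21. Other single libraries moved the Suffolk counts by over 1.5 times: day 3 to 120 without Suffolk day 0 replicate 3, 43 without Suffolk day 0 replicate 10, and 27, 20, 16 and 32 without Suffolk day 3 replicates 11, 13, 15 and 18. Day 7 moved to 417 and 109 without Suffolk day 7 replicates 21 and 28, and day 14 to 155 without Suffolk day 14 replicate 39. Day 21 moved to 172 and 36 without Suffolk day 0 replicates 3 and 10 and to 25, 24 and 17 without Suffolk day 21 replicates 42, 45 and 46.

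**Figure D3:**
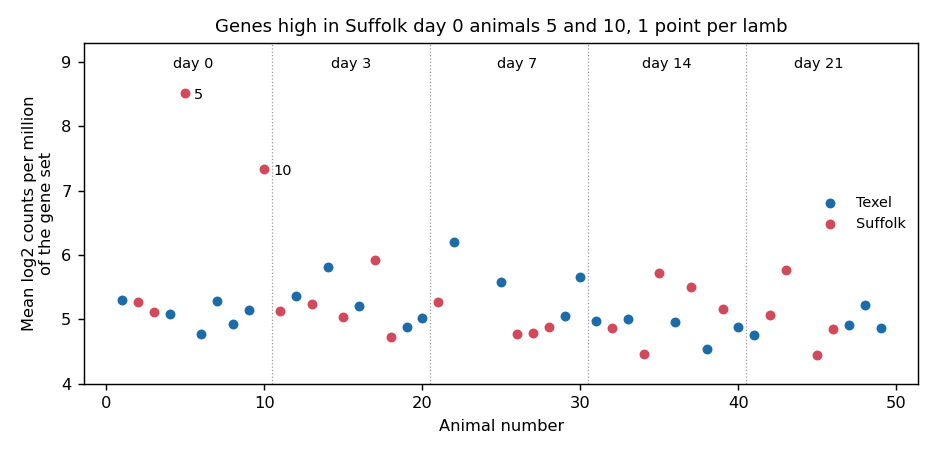
Mean log2 CPM of the 30 genes that were more than 2-fold higher in both Suffolk day 0 replicates 5 and 10 than in the other 8 controls, with 1 point per lamb by animal number, dotted lines between days. Animals 5 and 10 lie 3.40 and 2.22 above the mean of the other controls on the log2 scale, and the highest of the other 44 libraries lies 1.09 above it.

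The next question was whether the change from day 0 differed between the breeds. The breed by day interaction over all 4 infected days called 0 of 13199 genes (edgeR, 4 degrees of freedom, lowest adjusted p = 0.176), with 333 genes at an unadjusted p under 0.05, and a DESeq2 likelihood ratio test called 26. Tested by day, 20 genes passed in edgeR at day 7 (35 in DESeq2, and 10 with no low-count filter), and the median log2 fold change of these was 0.68 in Texel and −2.67 in Suffolk. None of the 20 passed as changed in Texel and all 20 passed as lower in Suffolk, and in all 20 the highest control was Suffolk day 0 replicate 5. The count was 0 without that library, Suffolk day 0 replicates 5 and 10 together, Texel day 7 replicate 22 or Suffolk day 7 replicate 26. It was also 0 with the index tag or animal number in the model and in a fit to the compared groups alone. At day 0 only Suffolk replicates 5 and 10 carried their index tag, so the tag term also takes in part of their difference from the other controls. Without Suffolk day 0 replicates 2, 3 and 10 the count was 43, 39 and 11, and without Texel day 0 replicates 4, 6 and 8 it was 9, 7 and 7. Without Texel day 7 replicates 25 and 30 it was 9 and 4, and without Suffolk day 7 replicate 27 or 28 it was 3. At days 3, 14 and 21 edgeR called 0 genes, with 375, 410 and 580 at an unadjusted p under 0.05, and DESeq2 called 16, 0 and 0. Without Suffolk day 0 replicates 2 and 3 edgeR called 31 and 30 genes at day 3, and 30 and 31 over all days, and without replicate 2 it called 1 at day 21. The rise of ENSBTAG00000047632 at day 7, 6.47 in Texel and 3.43 in Suffolk on the log2 scale, differed between breeds by 3.04 ± 0.86, which did not pass (edgeR adjusted p = 0.328 for day 7).

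Log2 fold changes at day 7 correlated between the breeds across the 13199 genes with r = 0.503 and rho = 0.487. The libraries of the 2 breeds, controls included, are separate, and genes are not independent replicates, so no p is given. Of the 895 genes that passed in Texel, 842 (94.1%) had the same direction in Suffolk, and 131 passed in both, 114 higher and 17 lower, where independent lists would share 6.43 higher and 1.83 lower. At days 3, 14 and 21 the correlation was 0.383, 0.577 and 0.453. Of the Texel calls, 24 of 24, 485 of 497 and 299 of 312 had the same direction in Suffolk at these days. Of the Suffolk calls, 43 of 72, 180 of 223, 250 of 268 and 93 of 105 had the same direction in Texel at days 3, 7, 14 and 21, and at day 7 these were all 144 of the higher ones and 36 of the 79 lower ones. Without Suffolk day 0 replicates 5 and 10, a fit that called fewer genes, 5 of 5, 77 of 78, 23 of 24 and 11 of 13 Suffolk calls had the same direction, with 40 of the 78 lower in Suffolk. At day 7 that fit lost 167 of the 223 Suffolk calls. Its correlation between the breeds over all genes was lower, at 0.328, 0.498, 0.501 and 0.373 at days 3, 7, 14 and 21.

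**Figure D4:**
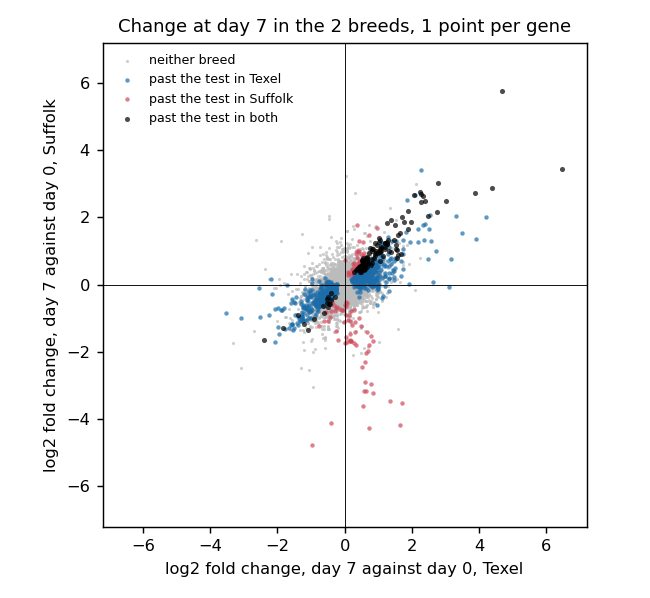
Log2 fold change at day 7 against day 0 in Texel (horizontal) and Suffolk (vertical), with 1 point per gene, coloured by the breed in which the gene passed the test (edgeR, adjusted p under 0.05). The 131 genes that passed in both breeds lie in the upper right (114) and lower left (17). Some genes that passed as lower in Suffolk lie at positive values in Texel in this fit to all libraries. Without Suffolk day 0 replicates 5 and 10 the direction was that of Texel in 77 of 78 Suffolk calls. That fit lost 167 of the 223 Suffolk calls, and its correlation over all genes was 0.498 against 0.503 with all libraries.

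The last comparison was between the breeds themselves. Averaged over the 5 days, the counts of 758 genes differed between Texel and Suffolk, 355 higher in Texel and 403 lower, and 57 by more than 2-fold. Counts cover aligned reads only, and whether sequence differences between the breeds changed alignment to these genes was not tested. ENSBTAG00000002448 was at 5.79 ± 4.87 CPM in Texel (n = 24) and 0.431 ± 1.03 in Suffolk (n = 22), a log2 difference of 4.01 ± 0.58 (edgeR adjusted p = 1.15e-05). Its counts were low in Suffolk, with 2 reads at day 0, where the ratio of Texel to Suffolk was 57.4 with a 95% counting interval of 15.7 to 478. At day 7 the ratio was 41.0 (6.90 to 1663), while at day 14 the means were closer, 3.12 CPM in Texel and 0.813 in Suffolk. ENSBTAG00000010070 was at 15.7 ± 13.2 CPM in Texel and 1.72 ± 2.51 in Suffolk, a log2 difference of 3.22 ± 0.53 (edgeR adjusted p = 0.000109). Neither of these 2 genes was among those called at day 14. ENSBTAG00000010610 was lower in Texel, with a log2 difference of −4.40 ± 0.34 (edgeR adjusted p = 6.69e-13), at 0.257 ± 0.263 CPM against 5.37 ± 2.84 in Suffolk. ENSBTAG00000031377 was also lower, with a log2 difference of −4.37 ± 0.42 (edgeR adjusted p = 9.43e-10), at 0.176 ± 0.279 CPM against 4.06 ± 2.64. In Texel these last 2 genes had 25 and 17 reads over all 24 libraries. At day 14 the ratio of Suffolk to Texel was 51.8 (95% counting interval 14.0 to 432) for ENSBTAG00000010610, an interval that leaves out the spread between lambs (edgeR adjusted p = 9.22e-05 at that day). For ENSBTAG00000031377 the ratio was 46.1 (12.2 to 391) at day 0, 39.5 (10.6 to 331) at day 3 and 25.7 (8.52 to 127) at day 14. In edgeR it passed at days 0, 3 and 7 (adjusted p = 0.00351, 0.0147 and 0.0386) and not at days 14 and 21 (adjusted p = 0.0708 and 0.262).

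Within single days, 90 genes differed between the breeds at day 0 (12 higher in Texel, 78 lower), 24 at day 3, 14 at day 7, 4 at day 14 and 6 at day 21. With the index tag in the model 21, 12, 9 and 1 passed at days 0, 3, 7 and 21, in a fit to the compared groups alone 22 and 1 at days 0 and 21, and with terms for animal number 1 at day 21. DESeq2 called 42, 18 and 10 genes at days 3, 14 and 21. Of the 78 genes lower in Texel at day 0, 29 belonged to the set that was high in Suffolk day 0 replicates 5 and 10. The count of 90 became 15 without replicate 5, 8 without both and 144 without Suffolk day 0 replicate 3. Since only replicates 5 and 10 carried their index tag at day 0, the fit with the tag is not separate from them. With all libraries in edgeR 2 genes passed at all 5 days, ENSBTAG00000010610 and ENSBTAG00000000295, but not both in the fits that called only 1 gene at day 21 (index tag, compared groups alone, animal number and single libraries left out). The latter was chosen after its values were seen, as were ENSBTAG00000008717 and ENSBTAG00000021284, which with these 2 made up the 4 genes called at day 14. ENSBTAG00000000295 was lower in Texel at each day, with log2 differences of −2.34 ± 0.23, −2.39 ± 0.25, −2.30 ± 0.27, −1.86 ± 0.24 and −2.25 ± 0.26 at days 0, 3, 7, 14 and 21 (edgeR adjusted p from 3.66e-09 to 1.77e-05). No Texel library (2.66 to 7.50 CPM) reached the lowest Suffolk library (10.7 CPM). The log2 differences of ENSBTAG00000008717 and ENSBTAG00000021284 at day 14 were −0.45 ± 0.08 and −2.22 ± 0.41 (edgeR adjusted p = 0.00930 for both). The count of 24 at day 3 fell to 5, 12, 8, 14 and 11 without Suffolk day 3 replicates 11 and 15 and Texel day 3 replicates 14, 12 and 19. The count of 14 at day 7 fell to 9 without Suffolk day 7 replicate 21 or 28 and to 7 without Texel day 7 replicate 29 or 30. The count of 4 at day 14 became 9, 7 and 2 without Texel replicate 31, Suffolk replicate 35 and Texel replicate 36. The count of 6 at day 21 became 1 without Texel replicate 41, 47 or 48 or Suffolk replicate 45, and 2 without Suffolk replicate 46 or Texel replicate 49. In a fit with added terms for animal number, a split found after the data were examined, lambs with lower and higher numbers within a day differed in 914 genes at day 7 and 398 at day 14 (edgeR). In that same fit the breeds differed in 12 and 4 genes at these days.

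**Figure D5:**
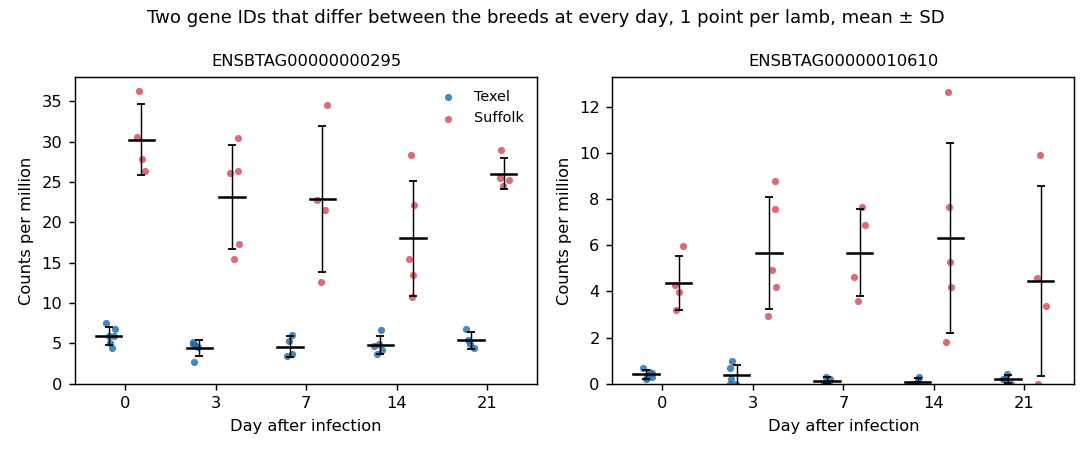
CPM of ENSBTAG00000000295 and ENSBTAG00000010610 by day after infection and breed, with 1 point per lamb, a bar at the group mean and whiskers of 1 SD. Every Suffolk library held at least 10.7 CPM of the first and every Texel library at most 7.50 CPM, and the second averaged 5.37 CPM in Suffolk and 0.257 CPM in Texel, with 1 Suffolk library of day 21 at 0 reads.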

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

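Chosen only after the result was seen were the tests of the index tag, of genes that vary together, of animal 5 alone and together with animal 10, of the breed gap by shuffling and by the interaction, of a batch by animal number, and all counts over other splits of the libraries. The tests of depth, of the number of Texel controls, and of index tag and reads behind the animal number difference were set before their results were known.

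In Suffolk day 0 animals 5 and 10, 30 genes stood more than 2-fold above all other controls, against at most 3 genes for any of the other 44 pairs of controls. The mean height of the other 6 libraries with their index tag over the rest of their groups was −0.038 (log2), and depth predicted at most 0.047, against observed heights of 3.40 and 2.22, so the tables argue against both. Over the other 44 libraries the same genes correlated with a mean r of 0.624, above the highest of 1000 random gene sets (0.110), which is consistent with a group of genes that varies together between lambs, of a process left open without gene names. Leaving out Suffolk day 0 animals 5 and 10 gave 5 Suffolk calls at day 3 and 78 at day 7. But the 3 pairs of controls with animal 5 all gave few (0 to 5 and 44 to 78). The pairs without it gave at least 72 and 103. Suffolk day 0 animal 5 alone, rather than both, may thus account for much of the Suffolk count at day 3, which was 0 without it. At day 7 the count was 133 without animal 5 and 109 without Suffolk day 7 replicate 28, so it did not rest on animal 5 alone.

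At day 7, 895 genes passed in Texel and 223 in Suffolk. With 4 of the 6 Texel controls the median count over 15 subsets was 573 (lowest 349), which argues against the number of controls as the whole cause. Of 100 groupings with the breed shuffled within each day, the real one included, 19 gave a gap as large. The highest gap was 2209, so chance differences between lambs could give it. Without animals 5 and 10 the interaction at day 7 called 0 genes in edgeR (20 with them, the difference between breeds that drew attention here). Whether the 2 breeds answer the infection differently stays open. That test recovered 2.99% of simulated 1.5-fold, 26.9% of 2-fold and 74.2% of 3-fold interactions, at a dispersion of 1.5 times the fitted trend. The bound was first set at over 80% recovery of 3-fold interactions in the test over all days, where 83.3% were recovered and the 0 would have counted against such a difference, and both the fold and the simulated test were changed after the result was seen.

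Lambs with lower and higher animal numbers differed in 914 genes at day 7 (488 higher and 426 lower in the higher numbers) and 398 at day 14 (93 and 305), in a fit with terms for breed and number, a split first met as the highest among random splits and then tested on the same libraries. With the index tag in the model 879 genes passed over both days together, and with the number of reads per library 1538, so the tables argue against both as the whole cause. At day 14 the shares of reads differed between lower and higher numbers (not aligned 45.5% ± 0.249 against 46.3% ± 0.350, outside annotated genes 24.0% ± 0.738 against 22.3% ± 0.384), each with an exact two-sided permutation p of 0.00794, the smallest 5 against 5 lambs can give, and 0.0397 adjusted over 10 tests. The split was picked for its gene count on these same lambs, so these p do not allow for that choice if the shares follow expression. A batch that follows the animal number at day 14 stays possible, but the labels name none. At day 7 neither share passed (adjusted permutation p 0.214 and 0.722), with the share not aligned lying the other way (46.7% in lower numbers, 45.4% in higher). At day 21 that share was 45.7% and 44.5% (exact permutation p 0.0286, adjusted 0.0952), with 0 genes between the numbers in edgeR (338 at an unadjusted p under 0.05). Of the 914 genes of day 7, 720 had the same direction at day 14, no biological explanation was tested, and since the numbers run in consecutive blocks by day, a batch by number across days cannot be told apart from the day of infection in any contrast between days.

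Of 200 groups tested for a library far from the others, 19 held 1, where chance marks about 1 in 20 groups. Suffolk day 14 replicate 35 held 8.27 M counts (others at most 4.28) and Suffolk day 21 replicate 42 held 7.95 M (others at most 3.91). In Suffolk day 0 replicate 2, 47.9% of reads were not aligned, against at most 45.5% in the other 3. In CPM, ENSBTAG00000020022 stood low in Texel day 14 replicate 40 (1.74) and Suffolk day 14 replicate 39 (0.720), and ENSBTAG00000011976 in Suffolk day 0 replicate 10 (18.5) and Texel day 14 replicate 38 (2.16). ENSBTAG00000044427 stood high in Suffolk day 0 replicate 2 (31.8). ENSBTAG00000047632 stood high in Suffolk day 3 replicate 17 (124) and Suffolk day 7 replicate 28 (1910) and low in Texel day 21 replicate 41 (393). ENSBTAG00000002448 stood high in Suffolk day 7 replicate 27 (0.193), Suffolk day 14 replicate 35 (3.49) and Suffolk day 21 replicate 43 (3.69). The value in replicate 27 is 1 read, in a group whose other 3 libraries held 0. ENSBTAG00000010070 was high in Suffolk day 14 replicate 35 (8.66) and low in Texel day 21 replicate 47 (1.77), and ENSBTAG00000031377 was high in Texel day 21 replicate 41 (1.19). ENSBTAG00000000295 was low in Texel day 3 replicate 12 (2.66), and ENSBTAG00000008717 high in Texel day 3 replicate 16 (184).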

How the results depend on the processing

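Chosen after the data were seen were the fits without Suffolk day 0 animals 5 and 10, those with animal number terms, and all settings of the interactions at single days and of the contrasts between infected days. No named gene changed direction under any of these settings. Apart from libraries left out 1 at a time, 124 counts stayed within 1.5 times and 51 moved, and 148 values of named genes kept their side of the threshold and 6 did not. Left out 1 at a time, libraries moved 88 counts, left 348 within 1.5 times and ended 13 calls of named genes. DESeq2 size factors in edgeR moved no count by over 1.5 times. The cause of the moves was not tested, except that fits with fewer libraries or groups have fewer degrees of freedom. No paired analysis was possible because each animal number stands in 1 group only.

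With no filter, Suffolk day 3 gave 39 genes, Suffolk day 21 63 and the day 7 interaction 10. With the index tag, Texel day 3 gave 9, Suffolk days 3, 7 and 21 gave 13, 133 and 4, the breeds at days 0, 3, 7 and 21 gave 21, 12, 9 and 1, and the day 7 interaction 0. With the compared groups alone, Texel day 21 gave 500, Suffolk 7, 15, 162 and 0 at days 3, 7, 14 and 21, the breeds 22 at day 0 and 1 at day 21, and the day 7 interaction 0. DESeq2 gave 87 for Texel day 3, 113, 423 and 160 for Suffolk days 3, 14 and 21, 42, 18 and 10 for the breeds at days 3, 14 and 21, 16 and 35 for the interaction at days 3 and 7, and 26 over all days. Without animals 5 and 10, both breeds gave 156, 750 and 276 at days 3, 14 and 21, Suffolk 5, 78, 24 and 13, the breeds at day 0 8 and the day 7 interaction 0. With animal number terms, Texel days 3 and 21 gave 78 and 203, Suffolk days 3 and 21 34 and 65, the breeds at day 21 1 and the day 7 interaction 0. Of the 1516 genes of day 7 over both breeds, 1037 passed without animals 5 and 10, as did 139 of 438 at day 3, 700 of 1620 at day 14 and 257 of 971 at day 21.

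With single libraries left out, both breeds gave 206 to 506 genes at day 3, 1155 to 2007 at day 7, 1057 to 1805 at day 14 and 505 to 1170 at day 21. Texel gave 7 to 68, 465 to 947, 307 to 553 and 101 to 346, and Suffolk 0 to 120, 109 to 417, 55 to 382 and 6 to 172. The lowest came without Suffolk day 0 replicate 5 for both breeds at days 3, 14 and 21 and Suffolk at days 3, 14 and 21. The breeds gave 671 to 827 over all days and 15 to 144, 5 to 32, 7 to 16, 2 to 9 and 1 to 4 at days 0, 3, 7, 14 and 21. The interaction gave 0 to 31 over all days, and 0 to 31, 0 to 43, 0 to 0 and 0 to 1 at days 3, 7, 14 and 21.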

Other observations

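The contrasts between infected days and all counts over other splits of the libraries were chosen after the results were seen.

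Between days 3 and 7, over both breeds, 744 genes changed, 503 higher and 241 lower, and 96 by more than 2-fold (edgeR, adjusted p under 0.05). From day 7 to day 14 edgeR called 0 genes, with 1360 at an unadjusted p under 0.05, and DESeq2 called 6. From day 14 to day 21 edgeR called 0 genes, with 805 at an unadjusted p under 0.05, and DESeq2 called 1. Between days 7 and 21, 328 genes changed, 198 higher and 130 lower, but 0 passed in edgeR without Suffolk day 21 replicate 45, 51 in a fit to the compared groups alone, 205 with no filter and 493 in DESeq2. Without single libraries that count was also 123 (Suffolk day 7 replicate 28), 138 (Texel day 21 replicate 47), 163 (Texel day 7 replicate 22), 180 (Texel day 7 replicate 29), 187 (Texel day 21 replicate 48), 218 (Texel day 7 replicate 30 or Suffolk day 21 replicate 46) and 692 (Suffolk day 21 replicate 42). The count of 744 was 494, 481 and 408 without Texel day 3 replicate 14, Texel day 7 replicate 25 and Suffolk day 7 replicate 28, and 482 in a fit to the compared groups alone.

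ENSBTAG00000010070 ranged from 0.472 to 44.7 CPM in the 24 Texel libraries, with none between 2.77 and 14.5 CPM. In addition, 2 Suffolk libraries, day 14 replicate 35 and day 21 replicate 42, held 8.66 and 10.1 CPM. These were also the libraries with the largest total counts, 8.27 and 7.95 M. The share of reads outside annotated genes was 22.3% ± 0.909 at day 7 (n = 8) and 23.5% ± 0.906 at day 0 (n = 10), exact two-sided permutation p = 0.00850, 0.0680 after adjustment over 8 tests.

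Splits of the same libraries into groups of the same sizes were counted, 100 for each contrast between days, the real one included. They test chance only, not a batch that follows the day. For both breeds the real split gave 438, 1516, 1620 and 971 genes at days 3, 7, 14 and 21, and the highest other split 32, 1, 140 and 1. For Texel the real counts were 895, 497 and 312 at days 7, 14 and 21 and the highest others 85, 18 and 8, and for days 7 against 3 the real count was 744 and the highest other 1. In each of these 1 of 100 splits, the real one, gave as many, the smallest share that 100 splits can give. The splits shuffled all days within a breed, so they stand for no difference between any days. Counts this large were rare in that case, but chance is not excluded for a single contrast.

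In 7 further contrasts few splits gave as many genes, but the real count fell to or under that of the highest other split when 1 or 2 lambs were left out. The other splits were not repeated without those lambs, so the fall may also reflect the smaller number of lambs. Chance differences between lambs are not excluded. For Texel at day 3 (24 genes, highest other 2, 1 of 100 splits) the 15 subsets of 4 of the 6 controls gave a median of 7 and a lowest of 0 genes in edgeR. For Suffolk at day 3 (72, highest other 38, 1 of 100) the count was 0 without Suffolk day 0 replicate 5 and 7 in a fit to the compared groups alone. For Suffolk at day 7 (223, highest other 73, 1 of 100) it was 133 without that replicate, 44 without replicates 2 and 5, and 15 in a fit to the compared groups alone. For Suffolk at day 14 (268, highest other 2, 1 of 100) it was 55 without replicate 5, 1 without replicates 2 and 5, and 162 in a fit to the compared groups alone. For Suffolk at day 21 (105, highest other 202, 3 of 100) the real count itself was lower, and it was 6 without replicate 5 and 0 in a fit to the compared groups alone. For the interaction at day 7 (20, highest other 15, 1 of 100) it was 0 without Suffolk day 0 replicate 5, Texel day 7 replicate 22 or Suffolk day 7 replicate 26, and with the index tag or animal number in the model. For days 21 and 7 (328, highest other 8, 1 of 100) it was 0 without Suffolk day 21 replicate 45.

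For the interaction over all days and at days 3, 14 and 21, and for days 14 against 7 and 21 against 14, the real count in edgeR was 0, so all 100 splits gave as many (highest others 1, 3, 10, 10, 0 and 4).

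For the breeds, the real split gave 758 genes over all days (highest other 13) and 24 at day 3 (1). In both, 1 of 100 splits was as large, which argues against chance. At day 21 the real split gave 6 genes (highest other 0) with 1 of 35, the smallest share that 35 splits can give. That count was 1 without Texel replicate 41, 47 or 48 or Suffolk replicate 45. It was 2 without Suffolk replicate 46 or Texel replicate 49, and chance is not excluded at day 21. In the breed comparisons too the other splits were not repeated with lambs left out, so such falls may also reflect fewer lambs. At day 0 (90 genes, highest other 83) 1 of 100 splits gave as many, but the split with 83 genes also put animals 5 and 10 on the same side, and the real count was 15 without Suffolk day 0 replicate 5 and 8 without both, so chance is not excluded. At day 7 (14 genes) 2 of 35 splits gave as many. The other of these gave 792, with animals 21, 22, 25 and 26 against 27 to 30, the split by animal number, in which each side held 2 Texel lambs. No further split reached 14, and with animal number in the model the breeds differed in 12 genes, but the share over all splits does not exclude chance. At day 14 (4 genes) 4 of 100 gave as many, and the highest gave 485, with animals 31 to 35 against 36 to 40. The real count was 2 without Texel day 14 replicate 36 and 4 with animal number in the model, and chance is not excluded. The splits with 792 and 485 genes called many times the real count and follow the animal number, which points to a structure of the samples. Their counts differ from 914 and 398 because they come from fits in which the split took the place of the breeds and the breeds of the other days were shuffled too. For the split by animal number itself, 1 of 34 splits gave as many as the 914 genes of day 7 (highest other 82) and 1 of 100 as many as the 398 of day 14 (highest other 277). Since it was picked as the highest of other splits of the same libraries, this rank was fixed beforehand and says nothing about chance.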
